A study of Homo sapiens with 8 samples.

How the data were processed

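RNA was measured in 8 libraries of HEK-293 cells that express PAR4 with a yellow fluorescent protein, 2 for each of 4 groups: wild type or labelled double knockout for β-arrestin 1 and 2, with control treatment or 30 µM AYPGKF-NH2. Per the labels, total RNA was purified on RNeasy mini columns, ribosomal RNA was depleted, and libraries were made with the ScriptSeq complete kit. The values deposited by the authors are raw counts per Ensembl gene, 60675 genes and 5 summary counts per library, with no normalization. The processing notes name STAR 2.5.3a and HTSeq 0.7.1. Their order, the genome build, the annotation release, the strand setting and the length of exposure are not given in the sources used here. One label spells the genotype in a way that could also be read as knockdown, and the series description gives a double knockout.

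Of the gene identifiers 57055 were found in GENCODE 29, which gave positions, exon lengths and types. Gene counts per library ranged from 6748461 to 23200982. Reads assigned to no gene are those the summary counts list as lying in no feature, and their share was taken of gene, ambiguous and unassigned reads together. Counting error on these shares was small (95% exact binomial intervals, 66.91% to 66.95% in the highest library). It covers counting only, since reads without molecular identifiers are not independent molecules. Levels are CPM as edgeR computes them on library sizes scaled by TMM, and the values for chemoreceptor genes use unscaled gene totals.

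Comparisons used edgeR 4.0.16 (R 4.3.3): TMM normalization, filterByExpr by group (24466 genes kept), a robust quasi-likelihood fit of 4 groups to all 8 libraries with 4 residual degrees of freedom, and two-sided quasi-likelihood F-tests. P values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The 5 comparisons were agonist against control within each genotype, the difference between these responses (interaction), and labelled knockout against wild type without and with agonist. The common dispersion was 0.0295, a coefficient of biological variation of 0.172. The standard error of a log2 fold change was taken as its size over the square root of F. With 2 libraries per group, leaving 1 out assumes that the lone library varies like the other groups.

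Before the data were examined, 24 gene lists with 583 genes were written down: β-arrestins, GRKs and PARs, immediate early genes, ERK feedback genes, SRF-MRTF and YAP-TAZ targets, NF-κB targets and chemokines, heterotrimeric G proteins with PLC-β and RGS, ER stress and amino acid response, heat shock response, cholesterol synthesis, glycolysis and hypoxia, p53 targets, cell division, extracellular matrix (ECM) and integrins, Wnt, Notch and Hedgehog targets, interferon-stimulated genes, neuronal lineage, kidney epithelial, haematopoietic and endothelial, fibroblast and stromal genes, mitochondrial transcripts, replication-dependent histones, ribosomal proteins and small structural RNAs. The result of 1 further list among them is not reported here. Lists were tested with limma 3.58.1 camera (preset correlation), beside camera with an estimated correlation and fry, adjusted over the lists within a comparison. Named genes followed a rule fixed at the same time: the largest changes among genes that passed at a mean of at least 2 CPM, ARRB1, ARRB2 and F2RL3 always, and up to 4 members of each list by smallest p. FOS, FOSB and EGR1, and EGR3, EGR2, NR4A1, NR4A2 and PTGS2 in the interaction, fall outside it.

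Alternatives were RLE size factors, no filter, a filter of at least 1 CPM in 4 libraries, an adjusted p below 0.01, glmTreat against a fold of 1.2, DESeq2 1.42.0, limma-voom, the library letter as a block, the 4 compared libraries alone, and leaving out each library. Chosen after seeing the data were the share of unassigned reads as a covariate, subtraction of a background estimated from 413 chemoreceptor genes (945 kb of exons), removal of GC and length trends, thinning of all libraries to the lowest total of gene counts, and protein-coding genes alone. The chemoreceptor genes were picked by family name and taken as silent, which was not checked. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

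The procedure was tested on simulated counts with planted changes, in 5 draws for each comparison. With dispersions drawn per gene, planted 4-fold changes were recovered in 93% (wild-type agonist), 92% (labelled-knockout agonist), 74% (interaction), 93% and 90% (genotypes without and with agonist) of cases, and 2-fold changes in 55%, 49%, 18%, 52% and 51%. False calls made up 8% to 10.9% of calls with dispersions drawn per gene, above the nominal 5%, and 3.7% to 5.5% with dispersions on the trend. These rates describe the simulated counts and need not carry over to the 8 libraries. Of simulated genes without a change 4.7% to 5% had an unadjusted p below 0.05. In the wild-type agonist comparison 554 genes did, where chance alone gives 1223. The simulated groups shared each gene's dispersion, while the measured groups differed in spread. The SD of log2 ratios of library A to B was 0.515 in labelled-knockout control and 0.307 to 0.349 in the other groups.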

Results

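Gene expression was measured in HEK-293 cells, a human embryonic kidney line, that express proteinase-activated receptor 4 (PAR4, encoded by F2RL3) together with a yellow fluorescent protein. Cells were labelled either wild type or double knockout for the adaptor proteins β-arrestin 1 and 2. They received a control treatment or 30 µM AYPGKF-NH2, a peptide that activates PAR4. The 4 groups held 2 libraries each, 8 in all, named A and B here after the labels. Gene counts summed to 18467336 and 20189165 in wild-type control, 17832328 and 23200982 in wild-type agonist, 7800059 and 11503377 in labelled-knockout control, and 7127623 and 6748461 in labelled-knockout agonist libraries. Reads assigned to no gene made up 21.9% ± 2.99 (SD, n = 4) of the reads in the wild-type libraries and 55.8% ± 9.9 (SD, n = 4) in the labelled-knockout libraries, with no overlap (two-sided exact permutation test, p = 0.0286, the smallest that 70 splits allow). The test ignores treatment and takes the 4 libraries of a genotype as independent, which the labels do not establish. The first principal component, with 65.2% of the variance, separated the genotypes. On the second, with 14.4%, labelled-knockout control libraries A and B lay at -96.8 and -21.1 and the other 6 between -0.7 and 52.5. The log2 ratio of library A to B across genes had an SD of 0.515 in labelled-knockout control and of 0.307 to 0.349 in the other groups.

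**Figure D1:**
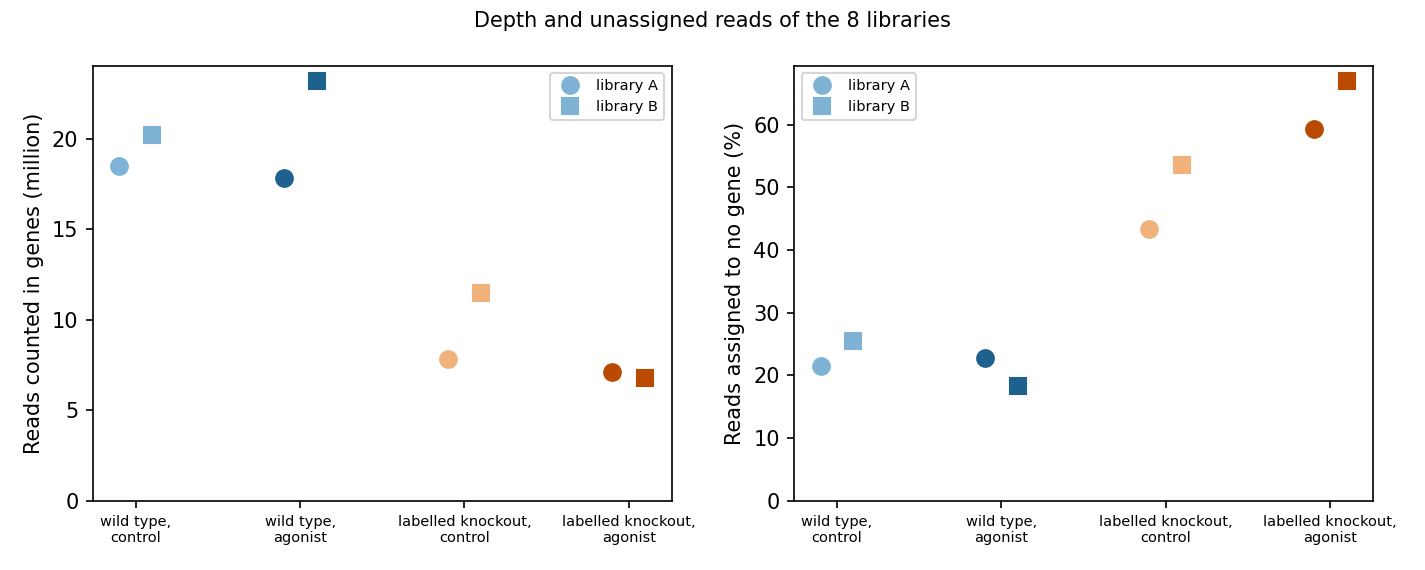
Reads counted in genes (left, axis in megareads) and reads assigned to no gene (right, % of all reads) in each of the 8 libraries, with circles for library A and squares for library B. The wild-type libraries reach at most 25.4% unassigned reads, and the labelled-knockout libraries start at 43.4%.

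The transcripts of the targeted genes were present in all 8 libraries. ARRB1 (β-arrestin 1, ENSG00000137486, chromosome 11, 75264182 to 75351705, GENCODE 29) stood at 9.07 ± 0.338 CPM (SD, n = 2) in wild-type control and 8.15 ± 1.28 CPM in labelled-knockout control libraries, a log2 fold change of -0.16 ± 0.26 (SE, adjusted p = 0.631). ARRB2 (β-arrestin 2, ENSG00000141480, chromosome 17, 4710489 to 4721499) stood at 30.3 ± 6.13 and 24.5 ± 0.354 CPM, a log2 fold change of -0.31 ± 0.21 (adjusted p = 0.264). With agonist both were lower in the labelled-knockout libraries, by log2 fold changes of -0.95 ± 0.27 (adjusted p = 0.00939) for ARRB1 and -1.01 ± 0.22 (adjusted p = 0.00168) for ARRB2. ARRB1 did not pass without wild-type agonist library B (adjusted p = 0.0879) or labelled-knockout agonist library B (adjusted p = 0.0759). Neither of these calls held once trends with GC content and gene length were removed (-0.42 and -0.35, adjusted p = 0.173 and 0.13). That setting also moved the median over all genes from 0.04 to 0.407. At a mean of at least 2 CPM over the agonist libraries, 5276 genes were called lower and 1556 higher in this comparison. The lower values of ARRB1 and ARRB2 with agonist were therefore not shown to be particular to them. The position and kind of the knockout lesions are not given in the sources used here, so whole-gene counts do not check the genotype, and groups are named by their labels throughout.

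F2RL3, the receptor gene itself (ENSG00000127533, chromosome 19, 16888860 to 16892606), was far higher in the labelled-knockout libraries. Its counts do not separate the introduced receptor from the cells' own. The levels were 42.3 and 14.9 CPM in wild-type control, 55.6 and 39.5 CPM in wild-type agonist, 1950 and 300 CPM in labelled-knockout control, and 805 and 977 CPM in labelled-knockout agonist libraries. The genotype log2 fold change was 5.30 ± 1.23 without agonist (adjusted p = 0.0354) and 4.23 ± 1.16 with it (adjusted p = 0.0421). All 4 labelled-knockout libraries lay above all 4 wild-type libraries, but neither adjusted p was firm. With 1 library left out the first fold change lay between 3.31 (adjusted p = 0.0521, without labelled-knockout control library A) and 6.21 and failed the test in 7 of 8 fits. The second lay between 4.01 and 4.45, and failed without any 1 of the wild-type libraries or labelled-knockout agonist libraries (adjusted p = 0.0642 to 0.194). F2RL3 did not pass the test for an agonist effect in wild-type cells (log2 fold change 0.73 ± 1.05) or in labelled-knockout cells (-0.34 ± 1.01). F2RL1, which encodes the related receptor PAR2, was lower in the labelled-knockout libraries, by -2.49 ± 0.20 without agonist (adjusted p = 1.16e-07) and -2.77 ± 0.21 with it (adjusted p = 7.3e-08).

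**Figure D2:**
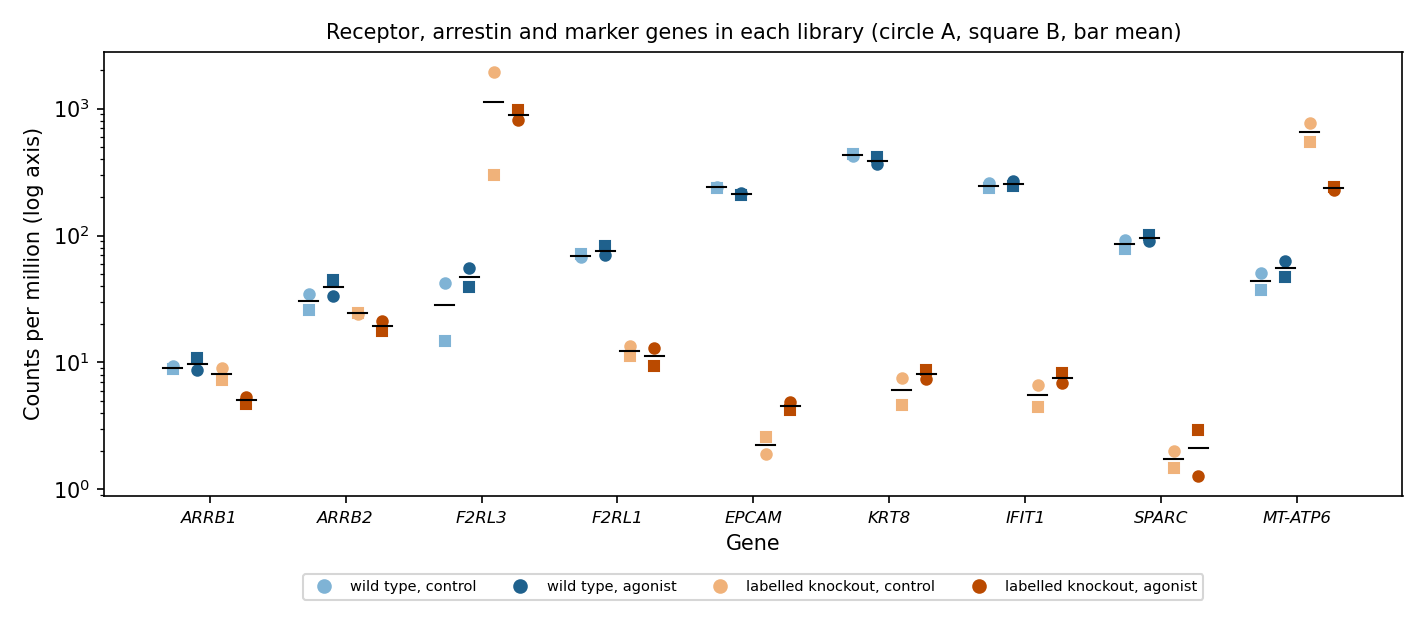
CPM (log axis) of 9 genes in each library, with circles for library A, squares for library B and bars at the group mean. ARRB1 and ARRB2 are present in all groups, F2RL3 is highest in the labelled-knockout libraries, and EPCAM falls from 239 ± 1.92 CPM in wild-type control to 2.25 ± 0.482 CPM in labelled-knockout control libraries (SD, n = 2).

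The comparison of agonist with control in wild-type cells asks which transcripts PAR4 activation changes when β-arrestins are present. The 5 genes that passed the test all rose, and 4 of them encode early-response transcription factors. EGR3 (zinc-finger factor, ENSG00000179388, chromosome 8, 22687659 to 22693302) rose from 0.941 ± 0.0824 to 23.8 ± 5.08 CPM (SD, n = 2), a log2 fold change of 4.65 ± 0.48 (adjusted p = 0.00485). The orphan nuclear receptor NR4A1 rose by 2.99 ± 0.33 (adjusted p = 0.00111), EGR2 by 2.94 ± 0.37 (adjusted p = 0.0044) and NR4A2 by 2.07 ± 0.28 (adjusted p = 0.0065). PTGS2, the inducible cyclooxygenase, rose from 3.96 ± 0.648 to 12.4 ± 0.502 CPM, by 1.64 ± 0.27 (adjusted p = 0.0442). NR4A1 passed whichever library was left out. EGR3 and NR4A2 did not pass without either wild-type control library or wild-type agonist library A (adjusted p up to 0.337), EGR2 without wild-type control library B (adjusted p = 0.135), or PTGS2 without any 1 of the 4 wild-type or 2 labelled-knockout agonist libraries (adjusted p up to 0.774), while their fold changes stayed between 1.49 and 4.74.

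FOS, FOSB and EGR1, chosen after their values were seen, had log2 fold changes of 3.29 ± 1.05, 4.46 ± 0.69 and 2.44 ± 1.00 and did not pass the test over 8 libraries. FOS stood at 2.87 ± 0.618 CPM in wild-type control and 28.3 ± 2.18 CPM in wild-type agonist libraries (SD, n = 2). In a fit to the 4 wild-type libraries alone these 3 passed, with adjusted p = 8.78e-06, 7.65e-07 and 0.00302. Labelled-knockout control libraries A and B held 16.7 and 1.48 CPM of FOS, 12.8 and 2.88 CPM of FOSB, and 28.3 and 3.48 CPM of EGR1. This spread enters the fit over 8 libraries. Library A also lay above B for EGR3 (4.05 and 0.961 CPM) and NR4A1 (3.22 and 1.55 CPM), while EGR2 stood at 1.55 CPM in both.

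Among 30 tested members of the immediate early gene list 4 rose and 0 fell, and 17 rose adjusted over the list alone. The list's median log2 fold change was 1.06 and its camera adjusted p was 1.1e-76, against adjusted p = 0.10 with an estimated correlation. Of 21 tested NF-κB targets and chemokines 1 passed, PTGS2, and 4 rose adjusted over the list alone (camera adjusted p = 9.7e-11, adjusted p = 0.10 with an estimated correlation). CXCL8, which encodes a neutrophil chemokine, had a log2 fold change of 0.86 ± 0.21 and did not pass singly. None of 29 targets of the actin-regulated SRF-MRTF and YAP-TAZ programmes passed singly, and 4 rose adjusted over the list alone (camera adjusted p = 9.9e-09, adjusted p = 0.49 with an estimated correlation). CCN1 and CCN2, both matricellular genes in that list, had values of 1.79 ± 0.43 and 1.10 ± 0.28. None of 13 mitochondrial transcripts passed singly, while the list's median was 0.28 (camera adjusted p = 5.1e-09, adjusted p = 0.49 with an estimated correlation, and camera adjusted p = 0.051 without wild-type agonist library A). MT-CO2 stood at 144 and 67.4 CPM in wild-type control and 206 and 172 CPM in wild-type agonist libraries (0.84 ± 0.31), and passed without wild-type control library A (adjusted p = 0.0114).

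In total 5 of 24466 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 554 had an unadjusted p below 0.05 where chance alone gives 1223. A fit to the 4 wild-type libraries called 16 genes, and leaving out either labelled-knockout control library called 30, against 1 without wild-type control library B and 2 without wild-type agonist library A. For the wild-type agonist comparison DESeq2 called 8 genes, and the library letter as a block gave 12. Subtracting an estimated background left 0 called, with EGR3 at 4.98 (adjusted p = 0.182) in a fit to 20399 genes with a median of 8.1 prior degrees of freedom, against 24466 genes and 13.6.

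**Figure D3:**
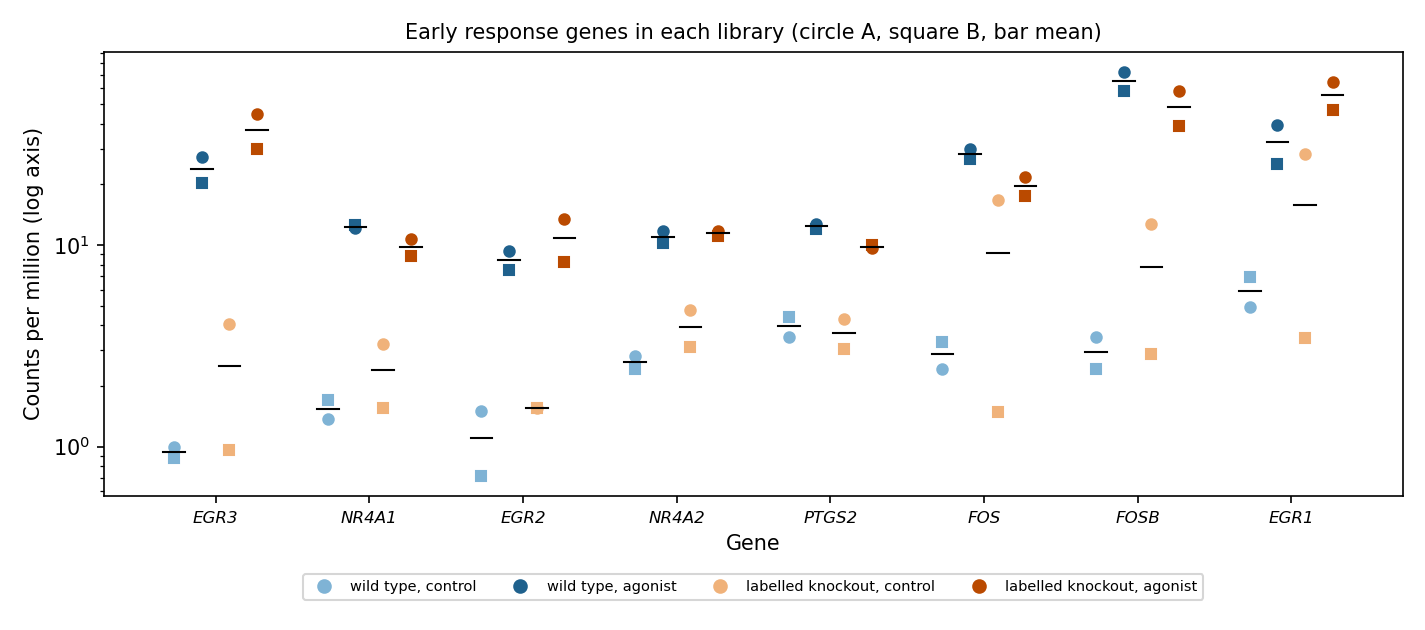
CPM (log axis) of 8 early-response genes in each library, with circles for library A, squares for library B and bars at the group mean. EGR3 goes from 0.941 to 23.8 CPM in wild-type and from 2.51 to 37.2 CPM in labelled-knockout cells. Labelled-knockout control library A lies above library B for FOS, FOSB, EGR1, EGR3 and NR4A1, but not for EGR2.

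The same comparison in labelled-knockout cells asks which changes the agonist gave in the libraries labelled as lacking β-arrestins. The 5 genes that rose in wild-type cells also rose here: EGR3 by 4.01 ± 0.46 (adjusted p = 0.000432), EGR2 by 2.80 ± 0.39, NR4A1 by 2.10 ± 0.34, NR4A2 by 1.57 ± 0.29 and PTGS2 by 1.44 ± 0.29 (adjusted p = 0.0054). Without agonist library A neither NR4A2 (adjusted p = 0.0525) nor PTGS2 (adjusted p = 0.0598) passed, and PTGS2 did not without agonist library B (adjusted p = 0.069). Independent lists of these sizes share 0.14 genes (Fisher's exact test, two-sided, p = 1.48e-08). The 2 comparisons share no library, but they share the estimate of each gene's spread, so the lists are not fully independent. The test also treats genes as independent. Of 30 immediate early genes 6 rose and 1 fell, and 11 rose adjusted over the list alone (camera adjusted p = 0.00035, adjusted p = 0.64 with an estimated correlation). Without labelled-knockout control library B that list no longer passed (camera adjusted p = 0.33).

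More genes fell than rose in these cells. Among the largest falls were those of RAB11B, a vesicle-recycling GTPase (12.7 ± 1.93 to 1.67 ± 0.00187 CPM, log2 fold change -2.93 ± 0.34, adjusted p = 9.3e-05), TUBB4A, a tubulin (-2.57 ± 0.45), NFIC, a transcription factor (-2.47 ± 0.33), and ZNF703 (-2.31 ± 0.26). In these 4 the labelled-knockout control libraries were the highest group. RAB11B stood at 2.77 ± 0.379 and 3.22 ± 0.408 CPM in wild-type control and agonist libraries, TUBB4A at 7.35 ± 2.24 CPM in labelled-knockout control and 1.17 ± 0.641 to 1.48 ± 0.111 CPM in the other groups, NFIC at 36.2 ± 19.9 CPM against 6.47 ± 0.823 to 9.12 ± 0.08 CPM, and ZNF703 at 106 ± 11.6 CPM against 13.4 ± 4.05 to 21.2 ± 7 CPM (SD, n = 2). Among the largest rises were those of the histone gene H2AC25 (44.4 ± 21.7 to 229 ± 56.7 CPM, 2.38 ± 0.30, with 242 ± 25.5 and 231 ± 25.5 CPM in wild-type control and agonist libraries), the small nuclear RNA 7SK (2.64 ± 0.49, adjusted p = 0.0249) and RN7SKP203 (2.71 ± 0.36), related to 7SK, so that reads of both are uncertain. The call of 7SK failed without either labelled-knockout control or wild-type agonist library (adjusted p up to 0.22).

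Of 36 heterotrimeric G protein, PLC-β and RGS genes 7 fell and 1 rose (camera adjusted p = 0.0011, adjusted p = 0.64 with an estimated correlation), including GNB1 (-1.73 ± 0.18), GNG4 (-1.62 ± 0.23) and GNAS (-1.18 ± 0.18). Of 13 mitochondrially encoded transcripts 5 fell (camera adjusted p = 4.7e-09, adjusted p = 0.64 with an estimated correlation), MT-ATP6 by -1.48 ± 0.20 and MT-CO2 by -1.77 ± 0.31, the latter not passing without any 1 of the 4 labelled-knockout libraries (adjusted p up to 0.218). ER stress and amino acid response genes rose in 7 of 25 and fell in 1 (camera adjusted p = 0.013, adjusted p = 0.64 with an estimated correlation), among them the ER-resident factor MANF (0.85 ± 0.16) and the cystine transporter subunit SLC7A11 (0.97 ± 0.19), which both missed the threshold without either agonist library (adjusted p = 0.0735 to 0.0901). The proliferation marker MKI67 fell from 1310 ± 177 to 507 ± 42.9 CPM (-1.37 ± 0.21), against 330 ± 74.7 and 391 ± 112 CPM in wild-type control and agonist libraries. Of 34 cell division genes 5 fell and 1 rose (camera adjusted p = 0.023, adjusted p = 0.64 with an estimated correlation). The high level of MKI67 was not typical of that list. In labelled-knockout against wild-type control libraries 17 of the 34 were lower and 1 higher (camera adjusted p = 0.00097, adjusted p = 0.24 with an estimated correlation). With agonist 24 were lower and 0 higher (camera adjusted p = 4e-07, adjusted p = 0.11 with an estimated correlation). The share of unassigned reads was 48.5% ± 7.21 in labelled-knockout control and 63.1% ± 5.37 in labelled-knockout agonist libraries (SD, n = 2). 7SK and the signal recognition particle RNAs RN7SL1 and RN7SL2 took 0.84% ± 0.156 and 2.315% ± 0.629 of their gene counts, against 2.405% ± 1.294 and 2.69% ± 0.481 in wild-type control and agonist libraries.

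For the labelled-knockout agonist comparison 1844 of 24466 genes passed, 667 higher and 1177 lower. Leaving out 1 library moved this count to 384 (without agonist library B), 1136 (without agonist library A) and 3772 (without control library B). With the share of unassigned reads as a covariate, chosen after seeing the data, 29 genes passed, and with the library letter as a block 2937 did. The fit gives each gene a single spread for all groups. Between libraries A and B the SD of log2 ratios was 0.515 in labelled-knockout control, against 0.307 to 0.349 elsewhere. P values can therefore be too small in comparisons that include that group, the interaction among them, and too large in wild-type cells. The counts of 5 and 1844 genes thus do not compare the sizes of the agonist responses.

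**Figure D4:**
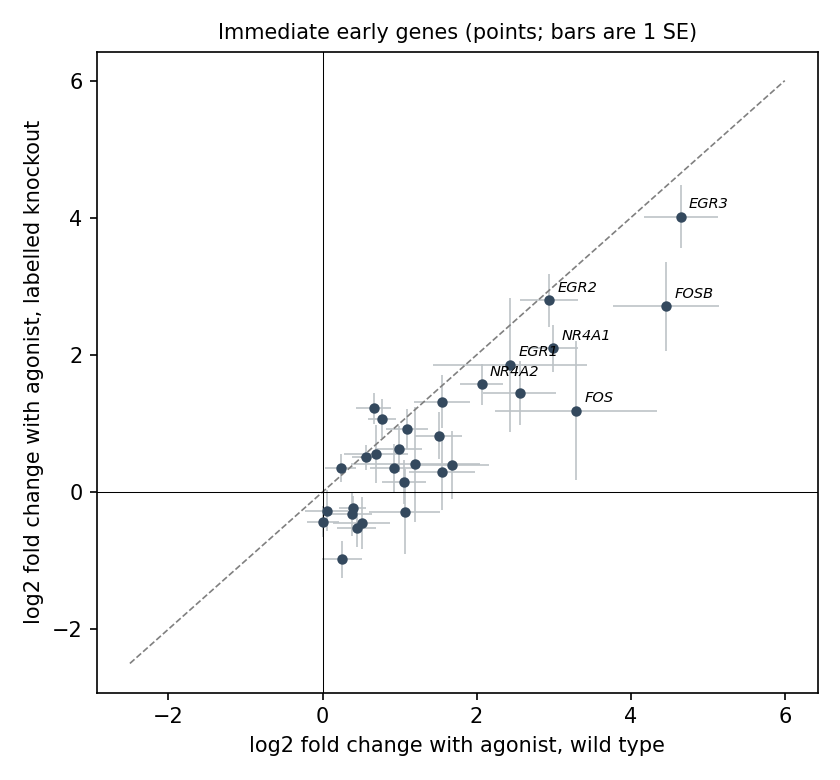
Log2 fold change with agonist in wild-type cells (x axis) against labelled-knockout cells (y axis) for the 30 tested immediate early genes, with bars of 1 SE and a dashed line of equal change. EGR3 lies at 4.65 and 4.01, and FOS, at 3.29 and 1.19, has wide bars in both directions.

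The interaction asks whether the agonist response itself differed between the genotypes. For the early-response genes no difference passed the test. The differences, labelled knockout minus wild type, were -0.64 ± 0.68 for EGR3, -0.14 ± 0.53 for EGR2, -0.89 ± 0.48 for NR4A1, -0.50 ± 0.41 for NR4A2 and -0.20 ± 0.39 for PTGS2, genes chosen here after their values were seen. With standard errors of 0.39 to 0.68 on 2 libraries per group, these values do not show equal responses. None of 30 immediate early genes passed singly, and the list's median of -0.63 passed by camera (adjusted p = 0.00086, adjusted p = 0.59 with an estimated correlation). Without labelled-knockout control library A the list's direction turned upward and it did not pass (camera adjusted p = 0.78).

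Most genes that passed had a lower log2 fold change with agonist in labelled-knockout than in wild-type cells. This need not be a weaker rise: those named below with a lower value fell in labelled-knockout cells. Mean levels of ACTB went from 535 to 707 CPM in wild-type and from 1120 to 428 CPM in labelled-knockout libraries. In the same order GNB1 went from 218 to 182 and from 332 to 100 CPM, and MT-ATP6 from 44 to 55.2 and from 658 to 235 CPM. RAB11B differed by -3.15 ± 0.46 (adjusted p = 0.0021), NFIC by -2.79 ± 0.45, ACTB, cytoplasmic β-actin, by -1.79 ± 0.30 (10 named pseudogenes), and the focal adhesion gene ZYX by -1.90 ± 0.39 (adjusted p = 0.0158). Of 29 SRF-MRTF and YAP-TAZ targets 4 differed, all lower (camera adjusted p = 0.00055, adjusted p = 0.51 with an estimated correlation). Of the G protein list 6 of 36 were lower, among them GNB1 (-1.47 ± 0.25), GNG4 (-1.75 ± 0.31) and GNAS (-1.50 ± 0.25), for a camera adjusted p = 0.00086, against adjusted p = 0.51 with an estimated correlation. MT-ATP6 (-1.81 ± 0.29) and MT-CO2 (-2.61 ± 0.44) were among 3 of 13 mitochondrial transcripts that were lower (camera adjusted p = 5.6e-13, adjusted p = 0.51 with an estimated correlation). MANF (0.97 ± 0.23) and SLC7A11 (1.08 ± 0.27) were higher, and neither passed without wild-type control library A (adjusted p = 0.178 and 0.0967), wild-type agonist library B or either labelled-knockout agonist library (adjusted p up to 0.223). GNB1, GNG4, ZYX and MT-CO2 did not pass without labelled-knockout agonist library B (adjusted p = 0.0556 to 0.107), nor did ZYX without wild-type agonist library B (adjusted p = 0.0728) or wild-type control library A (adjusted p = 0.0542), or MT-CO2 without any 1 of the wild-type agonist or labelled-knockout libraries (adjusted p up to 0.18).

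For the interaction 606 genes passed, 128 higher and 478 lower. The count was 100 without labelled-knockout agonist library B, 198 without wild-type agonist library B, 263 and 283 without wild-type control libraries B and A, and 996 and 2858 without labelled-knockout control libraries A and B. It was 1548 with the library letter as a block, 1595 with no filter and 1090 with DESeq2. Of the settings chosen after seeing the data, removal of GC and length trends gave 362, and the share of unassigned reads as a covariate gave 0, with a median size of change of 0.549 against 0.578 and a median standard error of 0.803 against 0.538. Across all genes, which are not independent replicates, the log2 fold changes with agonist of the 2 genotypes had a Pearson correlation of -0.235 and a Spearman correlation of -0.292, and the former was -0.062 without wild-type control library B. The mean share of unassigned reads also moved in opposite directions with agonist. It went from 23.4% to 20.45% in wild-type libraries, which overlapped, and from 48.5% to 63.1% in labelled-knockout libraries. Whether this share has a part in the negative correlation was not tested.

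The comparison of genotypes without agonist describes what set the labelled-knockout cells apart before stimulation. EPCAM, an epithelial adhesion molecule, stood at 239 ± 1.92 CPM in wild-type and 2.25 ± 0.482 CPM in labelled-knockout libraries (SD, n = 2), a log2 fold change of -6.69 ± 0.22 (adjusted p = 2.04e-12). The keratin genes KRT8 (-6.20 ± 0.23) and KRT18 (-3.06 ± 0.18) were also lower, with counts made uncertain by 50 and 67 named pseudogenes. These 3 were not typical of their list: of 18 kidney epithelial genes 5 were lower, 4 higher and 9 not called, with a median of 0.33, a mean of -0.86 and camera pointing down (adjusted p = 6.5e-05, adjusted p = 0.072 with an estimated correlation). Of 20 interferon-stimulated genes 14 were lower and 1 higher (camera adjusted p = 5.6e-33, adjusted p = 0.072 with an estimated correlation). IFIT1, an antiviral RNA-binding protein gene, went from 247 ± 13.8 to 5.56 ± 1.58 CPM (-5.51 ± 0.22), and IFIT3 (-7.41 ± 0.26) and IFIT2 (-8.20 ± 0.31) were lower still. Of 21 NF-κB targets and chemokines 15 were lower, CXCL8 by -5.20 ± 0.31 (camera adjusted p = 1.3e-10, adjusted p = 0.078 with an estimated correlation).

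Extracellular matrix and integrin genes were lower in 15 of 31 and higher in 2 (camera adjusted p = 6.5e-10, adjusted p = 0.19 with an estimated correlation), with SPARC at -5.64 ± 0.28, TNC at -3.82 ± 0.20 and FN1, fibronectin, at -2.04 ± 0.20. Of 20 p53 targets 14 were lower (camera adjusted p = 5.4e-08, adjusted p = 0.11 with an estimated correlation), such as DDB2 (-2.00 ± 0.22) and BBC3 (-2.23 ± 0.25). Replication-dependent histone genes were lower in 23 of 33 (camera adjusted p = 1.2e-18, adjusted p = 0.069 with an estimated correlation), H1-3 by -2.88 ± 0.21. Lists of other functions also leaned lower. Of 40 ribosomal protein genes 19 were lower and 3 higher, and of 34 cell division genes 17 and 1. Over all 24466 genes tested 5032 were lower and 3432 higher. Calls were not split by level here, so these counts alone do not show a loss particular to a list. All 13 mitochondrially encoded transcripts were higher (camera adjusted p = 2.2e-35, adjusted p = 0.072 with an estimated correlation), MT-ATP6 by 3.90 ± 0.23, and mitochondrial transcripts took 0.12% ± 0.028 of gene counts in wild-type and 1.195% ± 0.233 in labelled-knockout control libraries (SD, n = 2).

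Between the genotypes without agonist 8464 of 24466 genes passed, 3432 higher and 5032 lower. With GC and length trends removed the split was 6308 higher and 3221 lower, and the median over all genes moved from 0.143 to 0.454. Leaving out wild-type control library A left 4871, and the share of unassigned reads as a covariate, chosen after seeing the data, left 336, with a median standard error of 0.986 against 0.376.

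The comparison of genotypes with agonist asks the same of stimulated cells. Its calls leaned by level: at a mean of at least 2 CPM over the agonist libraries 5276 genes were lower and 1556 higher. Below 2 CPM 290 were lower and 4910 higher. Camera sets a list against genes at all levels, so lists of well-expressed genes can pass as lower without a loss particular to them. IFIT3 was lower by -6.70 ± 0.25 (adjusted p = 1.04e-11), EPCAM by -5.54 ± 0.20, CXCL8 by -6.60 ± 0.34 and SPARC by -5.49 ± 0.28. Of 18 kidney epithelial genes 6 were higher and 5 lower (median -0.06, camera pointing down with adjusted p = 0.00016, adjusted p = 0.10 with an estimated correlation). In this comparison the interferon-stimulated (15 of 20 lower, 3 higher), NF-κB (16 of 21 lower) and histone (29 of 33 lower) lists passed with an estimated correlation as well (adjusted p = 0.043 for each). Of 29 SRF-MRTF and YAP-TAZ targets 19 were lower, CCN2 by -2.25 ± 0.32 and TAGLN2 by -2.01 ± 0.23 (camera adjusted p = 6.3e-06, adjusted p = 0.25 with an estimated correlation). With the share of unassigned reads as a covariate, chosen after seeing the data, CCN2 was 0.18 and TAGLN2 0.15, neither passing. Of 10 tested haematopoietic and endothelial genes 7 were higher, such as PTPRC, at 0.965 ± 0.0132 CPM in wild-type and 6.86 ± 1.17 CPM in labelled-knockout libraries (adjusted p = 0.13 with an estimated correlation for the list). PTPRC was -0.20 with that covariate and did not pass. Counts per kb in 413 chemoreceptor genes taken as silent, relative to all gene counts, were 0.030 ± 0.004 and 0.274 ± 0.08 CPM per kb in the same libraries (SD, n = 2).

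Between the genotypes with agonist 12032 genes passed, 6466 higher and 5566 lower. With GC and length trends removed the split was 8443 higher and 2524 lower, and the median over all genes moved from 0.04 to 0.407. The count was 6100 without wild-type agonist library B, 6199 without labelled-knockout agonist library B, 6922 with an estimated background subtracted and 6547 with all libraries thinned to the lowest total of gene counts. It was 7 with the share of unassigned reads as a covariate, with a median standard error of 1.586 against 0.383. Between the comparisons with and without agonist 1870 genes were higher in both (907 for independent lists) and 3475 lower in both (1145 for independent lists). A further 89 were higher without agonist but lower with it, and 2 the reverse. These comparisons share no library but share the estimate of each gene's spread, so the lists are not fully independent.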

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

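Apart from thinning to equal gene counts, whose bound was set before its result was seen, the tests of explanations in this part were chosen after the results were seen. The agonist response differed between the genotypes, by the test of the difference itself, for 606 genes. Among the named genes the difference, labelled knockout minus wild type, was -3.15 for RAB11B, -2.79 for NFIC, -2.61 for MT-CO2, -1.90 for ZYX, -1.81 for MT-ATP6, -1.79 for ACTB, -1.75 for GNG4, -1.50 for GNAS, -1.47 for GNB1, 0.97 for MANF and 1.08 for SLC7A11. List medians of the difference were -1.03 for mitochondrial transcripts, -0.73 for Wnt, Notch and Hedgehog targets, -0.63 for immediate early genes, -0.40 for ERK feedback genes, -0.38 for SRF-MRTF and YAP-TAZ targets, -0.36 for glycolysis and hypoxia, -0.26 for ECM and integrins, -0.23 for G proteins and -0.12 for cell division genes, and none of these 9 passed with an estimated correlation. Reads assigned to no gene, which the gene comparisons do not use, made up 43.4% and 53.6% of reads in the labelled-knockout control and 59.3% and 66.9% in the labelled-knockout agonist libraries, against at most 25.4% in wild-type libraries.

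The larger share of unassigned reads in the labelled-knockout libraries is consistent with a background spread over the genome, as genomic DNA gives. Counts per kb in chemoreceptor genes taken as silent, divided by the unassigned reads, lay within a factor of 1.44 over the 8 libraries while the share itself ran from 18.2% to 66.9%. The 2 genotypes did not overlap on this measure (0.104 to 0.109 and 0.13 to 0.15 counts per kb per megaread), so a single source for all libraries was not shown. Unspliced RNA as a source was not tested, and a biological difference between the genotypes stays open.

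Several technical explanations were weighed for the agonist calls and the differences in response in labelled-knockout cells. After a uniform background was subtracted, 91.1% of the agonist calls and 88% of the differences were called again, which argues against it as the whole cause. With gene counts thinned to the lowest total 85% of the differences were called again. This argues against the higher gene counts of the wild-type libraries as their source. It does not test low gene counts in the labelled-knockout libraries, since 3 of these 4 were near that total already. For the same reason the 95.1% of agonist calls called again decides nothing. With GC and length trends removed 72.5% of the agonist calls were called again, but 51.2% of the differences, between the bounds set for a decision. With the share of unassigned reads as a covariate 1.5% and 0% were called again, yet the median standard error grew from 0.397 to 0.608 and from 0.538 to 0.803 while the median size of change barely moved (0.469 to 0.449 and 0.578 to 0.549), so library quality and the agonist cannot be told apart there. Of the called genes 63.9% lay nearer to the wild-type level with agonist than without (73.5% of the higher, 58.5% of the lower, and 42.4% of all tested genes). These genes were chosen by that contrast, so the share does not decide whether the control libraries stood apart. A β-arrestin-dependent response stays open. F2RL3, the gene of the stimulated receptor, was also higher in all 4 labelled-knockout than in all 4 wild-type libraries. Whether receptor level has a part in the differences was not tested.

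In labelled-knockout cells with agonist 6466 genes were higher than in wild type, 4910 of them at a mean below 2 CPM. Of the genes with at least 2 CPM 80.9% were called higher again after background subtraction, which argues against that background as the whole cause for them. Of the 5276 genes called lower at that level 58.2% were called lower again. The median log2 fold change of those still tested moved from -0.87 to -0.67, so many of the lower calls depended on the subtraction. Of the genes called higher below 2 CPM 31.3% were called higher again. Of the genes called lower below 2 CPM 83.8% were called lower again. Of those still tested the shares were 54.3% and 85.9%. The rest concerns the genes called higher below 2 CPM. A background cause predicted that the median log2 fold change of those still tested would shrink. It did not, at 2.74 before and 2.93 after subtraction, but the subtraction itself chose which genes were still tested. The subtraction also took more from the labelled-knockout agonist libraries by construction (3% and 4.5% of gene counts, against 0.5% and 0.4% in wild type). For the genes below 2 CPM the background and a true difference therefore cannot be told apart.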

How the results depend on the processing

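Of the alternatives, the unassigned share as a covariate, background subtraction, removed GC and length trends, thinning to the lowest total of gene counts and protein-coding genes alone were chosen after seeing the data. RLE size factors and limma-voom left the 5 gene counts within 1.5 times, and so did each other alternative for the counts where it is not named. The cause of each change was not tested, except that a threshold of 0.01, glmTreat and fewer genes or libraries are stricter or smaller by construction. The wild-type agonist count of 5 became 17 with no filter, 12 with the library letter as a block, 16 with the 4 compared libraries, 8 with DESeq2 and 0 with background subtracted, and 1 to 30 with 1 library left out. The labelled-knockout agonist count of 1844 became 716 at 0.01, 2937 with the block, 1014 with glmTreat and 29 with the covariate, and 384 to 3772 with 1 library left out. The interaction count of 606 became 129 at 0.01, 1595 with no filter, 1548 with the block, 352 with glmTreat, 1090 with DESeq2, 0 with the covariate and 362 with GC and length trends removed, and 100 to 2858 with 1 library left out. Between genotypes without agonist, 8464 became 5038 at 0.01 and 336 with the covariate, and 4871 to 9086 with 1 library left out. Between genotypes with agonist, 12032 became 7008 at 0.01, 6204 with at least 1 CPM in 4 libraries, 7 with the covariate, 6922 with background subtracted, 6547 with thinning and 6507 with protein-coding genes alone, and 6100 to 15473 with 1 library left out. The correlation of agonist responses was -0.051 with no filter and -0.304 to -0.062 with 1 library left out. Genes higher in both genotypes numbered 9 with no filter, 10 with the block and 1 to 23 with 1 library left out.

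With an estimated correlation 0, 0, 0, 0 and 3 lists passed in the 5 comparisons, against 8, 8, 9, 14 and 19 by preset camera; fry left 0 in both agonist comparisons and the interaction, where no filter gave 15. With 1 library left out, lists numbered 6 to 11, 6 to 11, 7 to 14, 14 to 19 and 20 to 22. Values that changed sign were, with the covariate, F2RL3 with agonist in labelled-knockout cells 1.97, interaction EGR3 0.60 and EGR2 0.46, genotype without agonist ARRB1 0.67 and ARRB2 0.52, and genotype with agonist ARRB1 0.45, ARRB2 0.35, CCN2 0.18, TAGLN2 0.15 and PTPRC -0.20. With GC and length trends removed ARRB1 was 0.041 and ARRB2 0.064 without agonist. F2RL3 with agonist in labelled-knockout cells was 0.27 by limma-voom, 0.15 with the block and -1.16 to 1.57 with 1 library left out. With 1 library left out, interaction EGR3 was -1.48 to 0.61, PTGS2 -0.48 to 0.042 and EGR2 -0.79 to 0.35. Interaction EGR2 was 0.18 with background subtracted. The labels do not say whether libraries of the same letter share a batch or day, and the correlations of A minus B between groups were 0.371, 0.213, 0.125, 0.233, 0.015 and 0.156. Fewer gene counts in the labelled-knockout libraries limit what low-count genes can show.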

Other observations

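Further gene groups differed between the genotypes without agonist, where calls were not split by level. Of 23 cholesterol synthesis genes 13 were lower in the labelled-knockout libraries (camera adjusted p = 4.5e-05, adjusted p = 0.30 with an estimated correlation), STARD4, a sterol carrier, by -2.14 ± 0.20 and HMGCS1, an early enzyme of the pathway, by -1.38 ± 0.18 (SE). Of 22 neuronal lineage genes 10 were lower and 4 higher (camera adjusted p = 0.0028, adjusted p = 0.19 with an estimated correlation), with SOX11 at -5.03 ± 0.30 and MAP2 at -2.20 ± 0.20. Ribosomal protein genes were lower in 19 of 40 and higher in 3, and 4 of 8 small structural RNAs were lower (adjusted p = 0.40 and 0.19 with an estimated correlation). Neither of these last list calls held with GC and length trends removed.

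Of 27 glycolysis and hypoxia genes 9 were lower and 1 higher (camera adjusted p = 0.0058, adjusted p = 0.45 with an estimated correlation). Heat shock genes (6 of 16 lower, 2 higher, camera adjusted p = 0.10), fibroblast and stromal genes (3 of 12 lower, 1 higher, camera adjusted p = 0.60), and β-arrestins, GRKs and PARs (1 of 11 lower, 1 higher, camera adjusted p = 0.38) did not pass as lists. With agonist in wild-type cells, 0 of 19 ERK feedback genes passed edgeR's test singly (1 adjusted over the list alone, camera adjusted p = 8e-07, adjusted p = 0.49 with an estimated correlation), and 0 of 18 Wnt, Notch and Hedgehog targets did (camera adjusted p = 0.0026, adjusted p = 0.49 with an estimated correlation). With agonist in labelled-knockout cells 4 of 33 histone genes rose and 1 fell (camera adjusted p = 0.47), H2AC6 by 1.32 ± 0.18.

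Copy number differences between the cells were tested as a hypothesis, with the bound set before the result was seen. After GC and length trends were removed, chromosome medians of the genotype log2 fold change without agonist spanned 0.65, against 0.22 at the 95th percentile of 1000 shuffles, over 13930 genes. The span was 0.68 with agonist, and the medians of the 2 comparisons, which share no library, had a correlation of 0.96. Both compare the same labelled cells, so any lasting expression difference would give such a correlation, and it does not favour copy number. The shuffles also treat genes as independent. The span without agonist met the bound set for copy number differences, which were not measured. Chromosome accounted for 3.43% of the variance, which leaves most of the genotype difference open.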
